A study of Homo sapiens with 12 samples.

How the data were processed

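Gene expression was measured in 12 samples of MCF-7/AZ, a human breast cancer cell line of luminal origin, on 1-colour Agilent arrays labelled with Cy3. Per the labels, 1 line was a mock line and the other had been stably transduced with a retrovirus encoding human P-cadherin cDNA together with EGFP. Each line was given azurin, a copper protein of bacterial origin, at 100 µM for 48 h, or PBS buffer alone. This made 4 groups of 3 samples. The series design calls the 3 samples of a condition independent and treated with different production batches of azurin, so p-values measure the spread between such samples.

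The authors scanned each array and extracted spot intensity with Agilent Feature Extraction 10.7.3.1, per the file headers. The deposited processed signal is a linear intensity per spot from which Feature Extraction had subtracted the background within the array, with no scaling between arrays. The detrending settings behind it are not given in the sources used here. The same deposited tables hold the median spot brightness, the local background and flags for spots above background, saturated or outlying. A second deposited table gives 1 value per probe and array on the log2 scale. Each of its columns was set against the mean log2 processed signal per probe. The median difference was about 0 on every array, so no centring or scaling was found in it. A median does not show that the values of all probes were equal. Which steps the authors took after it is not given in the sources used here. Its column medians were 7.56, 7.46 and 7.6 for mock PBS arrays 1, 2 and 3, then 7.15, 7.66 and 7.57 for mock azurin, 7.3, 7.84 and 7.49 for P-cadherin PBS, and 7.86, 8 and 7.57 for P-cadherin azurin.

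Each array had 44495 spots and 34127 probes that were not controls. Control spots and outlying spots were left out, log2 of the processed signal was averaged over the spots of a probe, and the 75th percentile over probes was subtracted per array. A probe entered when it was well above background on all 3 arrays of at least 1 group, in at least a share of 0.5 of its spots. Probes were named by matching the files' accessions to a RefSeq table of assembly GRCh38.p14, used for names alone because the array's grid was annotated on another assembly, and no coordinates are given for that reason. Of the 34127 probes, 25771 matched a gene and 8356 kept their own identifier. A gene was represented by its brightest entering probe, which left 20043 genes for testing from 24457 entering probes. Of these, 15262 had a symbol and 4781 did not, and 3680 had several entering probes.

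Differences were fitted with limma 3.58.1 in R 4.3.3 over all 12 arrays, with a mean for each of the 4 groups and a shared, moderated variance, because 3 arrays per group give a poor estimate of the spread alone. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Besides the pairwise comparisons, the difference between the azurin effects of both lines (the interaction) and their mean were tested. Gene lists were tested with limma's camera at its preset correlation of 0.01, adjusted over the 37 lists of a comparison. An estimated correlation was run beside it and ended every list call, as stated with each list. The lists covered p53 targets, apoptosis regulators, lysosome, endocytosis, autophagy, cell junctions, integrins and laminins, matrix proteases, kinases, hormone response, lineage and stem markers, mesenchymal genes, cell cycle, ribosome biogenesis, immune and stress responses, metal handling, metabolism, histones, reference genes, and markers of fibroblasts, leukocytes, endothelium and blood or liver. Other R packages were data.table, version 1.17.8, and statmod 1.5.0.

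The groups, tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined. Named were CDH3, the gene of P-cadherin, and per comparison the 10 genes with the greatest rise and the 10 with the greatest fall among called genes with a symbol whose arrays did not overlap between groups. From each list past its test, up to 4 members with the smallest p were added among those that moved the way of the list. The direction of these members is therefore no support for the list. In the azurin comparisons, up to 4 members with the smallest p were also added from 7 lists, regardless of result and direction. Where fewer than 5 genes passed, the 5 smallest p in each direction were named too. Outside this rule, PLK2 and COL4A2 were named for P-cadherin without azurin and SGSH for azurin in the P-cadherin line. So were NUPR1 and SLC7A5 for P-cadherin with azurin. Other genes named outside the rule are marked as chosen after their values were seen.

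For a gene not well above background on any array of 1 group, the change is given as a bound. The brighter group's mean was set against the dimmer group's mean of the higher, per array, of the lowest signal among probes above background and the probe's own signal. No fold is given where both groups were below background. No spot was saturated. The number of arrays limits the precision, and 28 values in the tested matrix were missing.

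The headers showed 6 slides and 2 scan sessions. Mock PBS, mock azurin and P-cadherin PBS arrays shared slides 1, 2 and 3, with 1 array of each group per slide and the slide number equal to the replicate number of the labels. The 3 P-cadherin azurin arrays were on slides 4, 5 and 6 and were scanned in the second session. Every comparison that includes them is therefore confounded with that slide set and session, and the comparison of azurin in the mock line is not. On their slides, all mock PBS arrays held position 1, all mock azurin arrays position 3 and all P-cadherin PBS arrays position 4. The comparisons among these groups are therefore confounded with position on the slide.

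The replicate numbers come from the labels, which do not say that a number marks a shared batch or day. The pairing was checked by the correlation, across genes, of deviations from the group means. For arrays of the same number it was 0.385, 0.413 and 0.479 between mock PBS and mock azurin. It was 0.388, 0.437 and 0.57 between mock PBS and P-cadherin PBS, and 0.161, 0.295 and 0.607 between mock azurin and P-cadherin azurin. It was 0.0658, 0.325 and 0.197 between P-cadherin PBS and P-cadherin azurin. The rule of over 0.1 in every pair was met for the first 3 comparisons and not for the last. Between mock azurin and P-cadherin azurin, arrays of different numbers also reached 0.483 (1 with 2) and 0.324 (2 with 1), so that only number 3 stood out there. Numbers 1 with 2 and 2 with 1 gave 0.252 and 0.128 between mock azurin and mock PBS. Between mock PBS and P-cadherin PBS they gave 0.151 and 0.298. These were over 0.1 too, though below the same-number values, so meeting the rule does not by itself show pairing. For arrays of the same number the correlation was 0.236, 0.27 and 0.273 between mock PBS and P-cadherin azurin and 0.34, 0.148 and 0.387 between mock azurin and P-cadherin PBS, over 0.1 in every pair as well. In the latter, numbers 1 with 2 and 2 with 1 gave 0.192 and 0.16, above the 0.148 of number 2. Among the groups on slides 1, 2 and 3 a shared number was also a shared slide, while P-cadherin azurin shared a number and no slide with the others.

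The procedure was tested on simulated data for 20021 genes with complete values, of which 200 were changed. At a log2 change of 1, limma recovered 53% of them for P-cadherin without azurin, 53.5% for azurin in P-cadherin cells, 59.5% for azurin in mock cells and 2% for the interaction. The false calls were 7, 7, 6 and 0 in that order. At a log2 change of 2 it recovered 93%, 97.5%, 96% and 83%, with 8, 9, 7 and 5 false calls. With 1 of the 37 lists shifted by 0.3 in the comparison of azurin in mock cells, camera called 1 list. All simulated genes and arrays were drawn independently. The simulation therefore cannot show false calls from correlation between genes or from deviations shared by slide or replicate number.

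Alternatives were quantile normalization, scaling to the median of probes above background on all arrays, no filter on dim probes, a filter requiring all 12 arrays, the mean over a gene's probes, slide as a fixed block, the replicate block, only the compared groups in the fit, a trended and robust variance, array weights, the deposited log2 table, other thresholds and leaving out each array. Chosen after seeing the data were normexp with an offset of 50 on median signals, slide as a random block, the 75th percentile of shared detected probes, a fit without the arrays numbered 3, and covariances of fold changes with no effect that keep arrays of the same number paired, taken from deviations from the group means.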

Results

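Transcript levels were compared between a mock MCF-7/AZ line and its counterpart transduced to express P-cadherin, a cell-cell adhesion protein encoded by CDH3, each after 48 h with 100 µM azurin or with PBS. The title of the series names azurin as an anti-cancer protein and the lines as differing in P-cadherin, so the comparisons address what the transgene changes, what azurin changes in each line, and whether the azurin response depends on the line. There were 3 arrays in each of 4 groups. The 75th percentile of the processed signal lay between 1220 and 2184 over the 12 arrays, and replicate arrays of a group correlated at 0.983 to 0.993 across probes, which are not independent replicates. Signals well above background were found for 72.7% to 76.4% of probes on the azurin-treated P-cadherin arrays, which had slides and a scan session of their own, and for 62% to 67.5% on the others. Their local background was 29 to 36.5, against 38 to 40 for mock PBS, 43 to 47 for mock azurin and 43.5 to 46 for P-cadherin PBS. Each of these other groups kept a position of its own on the slides. Principal component 1 held 31% of the variance and component 2 held 22.4%, and the arrays numbered 3 stood apart from the other arrays of their groups.

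CDH3 had 1 probe on the array and was not higher on the arrays labelled P-cadherin. Its level, log2 relative to the array's 75th percentile, was 2.43, 2.25 and 2.42 on the mock PBS arrays and 1.97, 1.98 and 2.08 on the P-cadherin PBS arrays. The difference of -0.36 (SE 0.129, n = 3 per group) did not pass the adjusted test (adjusted p = 0.203), although no P-cadherin PBS array reached the lowest mock PBS array, and the slides gave -0.47, -0.27 and -0.34. The CDH3 difference was negative in every setting run and passed with array weights (-0.37, adjusted p = 0.0132) and with slide as a random block (adjusted p = 0.0483). With azurin the levels were 2.20, 2.08 and 2.51 on the mock arrays and 1.89, 1.89 and 2.04 on the P-cadherin arrays. The azurin effect on CDH3 was -0.07 in the P-cadherin line (adjusted p = 0.799) and -0.10 in the mock line (adjusted p = 0.786). Where this probe lies relative to the transferred cDNA is not given in the sources used here, so CDH3 does not check the labels, and directions below refer to the arrays labelled P-cadherin.

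**Figure D1:**
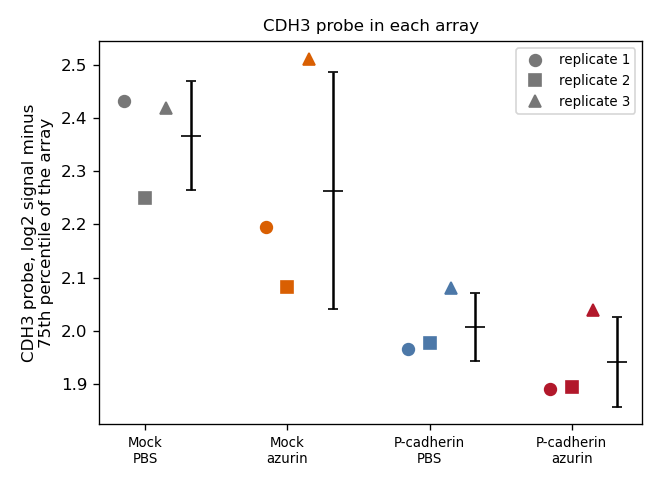
Level of the CDH3 probe on each of the 12 arrays, as log2 signal relative to the 75th percentile of the array, by group, with symbols for the replicate number and bars for the group mean and SD (n = 3). The P-cadherin PBS arrays lie at 1.97 to 2.08, below the mock PBS arrays at 2.25 to 2.43.

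Without azurin, some of the genes with the largest differences between the lines were above background in 1 line alone, and others were measured in both. SOX2, a transcription factor of stem cells, was at least 12.3-fold higher (adjusted p = 3.92e-05). MAGEA11, a testis-restricted antigen on the X chromosome, was at least 6.45-fold higher (adjusted p = 2.38e-07), and GABRA1, a subunit of the GABA-A receptor, at least 6.17-fold higher. SGCE, which encodes epsilon-sarcoglycan, fell by 3.84 on the log2 scale (SE 0.163, adjusted p = 9.34e-07), and PCDH10, a protocadherin, fell by 2.75 (SE 0.426, adjusted p = 0.00821), with its other probe at -4.28. The chloride channel regulator CLCA2 was at least 5.53-fold lower (adjusted p = 0.00655). In all, 453 of 20043 genes passed the adjusted test with limma, 231 higher and 222 lower, of which 420 changed at least 1.5-fold and 452 had the same sign on all 3 slides. The signs come from the arrays that gave the calls, so their agreement is no independent support. The median absolute log2 change of the called genes was 1.07.

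The other genes with the greatest rises were LRFN5 (at least 5.03-fold), RPRM (2.8), CCDC63 (2.36), XCL1 (2.36), GP2 (2.28), the proton-sensing receptor GPR65 (2.2) and the ephrin receptor EPHA6 (1.89), each as a bound because the mock arrays were below background. Among the falls, the signalling kinase IRAK2 was at least 2.41-fold lower, the protease ADAMTS1 at least 1.84-fold, the receptor kinase MERTK at least 1.7-fold and CADPS2 at least 1.65-fold lower. NXF2 fell by 2.49, VEPH1 by 2.29 and CLEC3A by 2.24 on the log2 scale. XCL1 and NXF2 have near-identical copies in the genome, so the transcript behind their probes is uncertain.

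Genes of the amino acid stress response driven by ATF4 were lower as a list in the P-cadherin line without azurin, with 27 of 29 measured members negative and a median of -0.51 (camera adjusted p = 2.42e-07). The call was lost with a correlation estimated from the data (adjusted p = 0.678 with an estimated correlation). NUPR1, a stress-induced chromatin protein, fell by 1.40 (SE 0.197, adjusted p = 0.00451) and SLC7A5, an amino acid transporter, fell by 0.99 (adjusted p = 0.0226). No member rose, and 5 fell when adjusted over the list alone. SLC3A2, the partner of SLC7A5, was at -0.76 (adjusted p = 0.105) and the asparagine synthetase ASNS at -0.84 (adjusted p = 0.11). The medians within slides 1, 2 and 3 were -0.333, -0.325 and -0.999.

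Direct targets of p53 were lower as a list, with 25 of 29 negative and a median of -0.30 (adjusted p = 0.00136; adjusted p = 0.775 with an estimated correlation). None of them fell past the test over all genes, 1 rose (the kinase PLK2, at 1.47), and 1 rose and 1 fell when adjusted over the list alone. With the replicate block 1 fell over all genes. The cell cycle inhibitor CDKN1A stood at -1.34 (adjusted p = 0.0603), GADD45A at -1.23 (adjusted p = 0.252), ZMAT3 at -0.65 and BTG2 at -0.63. The slide medians were -0.17, -0.11 and -0.59, and the list call ended without mock PBS array 3 (adjusted p = 0.214).

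Replication-dependent histone genes were lower as a list of 16 (adjusted p = 0.00136; adjusted p = 0.695 with an estimated correlation), with 2 that fell and 6 when adjusted over the list alone. H2BC21 fell by 0.85 (adjusted p = 0.0114), while its other probe showed 0.00, and H2BC12 fell by 0.58 (adjusted p = 0.0201), with -0.35 and no call at its other probe. H2BC5 was at -0.47 and H1-2 at -0.49. The median over the list was -0.13, and it was -0.14, -0.25 and -0.12 on slides 1, 2 and 3. Basal or myoepithelial markers were lower as a list of 22 (median -0.30, adjusted p = 0.00592; adjusted p = 0.678 with an estimated correlation), with no member called over all genes and 1 that fell when adjusted over the list alone. Keratins KRT16 and KRT17 were at -1.42 and -1.29 (adjusted p = 0.227 and 0.285), the laminin chain LAMC2 at -0.64 and the myosin kinase MYLK at -0.44. Members that fell over all genes numbered 2 with slide as a block and 5 with the replicate block, where 9 fell and 1 rose over the list alone. The slide medians were -0.28, -0.26 and -0.26, and the call ended without mock PBS array 1 (adjusted p = 0.118) or P-cadherin PBS array 3 (0.0526).

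Integrins and laminins, which share 4 listed genes with the basal markers, were lower as a list of 21 (adjusted p = 0.0364; adjusted p = 0.678 with an estimated correlation). LAMA3 fell by 1.06 (adjusted p = 0.0334) and COL4A5 by 0.99 (adjusted p = 0.0438), while COL4A2 rose by 0.87. Adjusted over the list alone, 1 rose and 4 fell. Over all genes, 1 rose and 4 fell with slide as a block, and 1 and 5 with the replicate block. Fibronectin, FN1, was at least 1.26-fold lower without passing the test (adjusted p = 0.112). The slide medians were -0.34, -0.15 and 0.00, and the call ended in 7 other settings, with adjusted p up to 0.252.

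DNA replication genes were higher as a list, positive in 40 of 40 members with a median of 0.29 (adjusted p = 0.00128; adjusted p = 0.835 with an estimated correlation), and none was called singly, over all genes or over the list alone. POLE was at 0.58 (adjusted p = 0.105), CDT1 at 0.75, the helicase subunit MCM5 at 0.88 (adjusted p = 0.189) and RFC3 at 0.46. This shift came from slide 3, whose median was 0.96 against 0.05 and 0.02 on slides 1 and 2, and the list median was -0.05 without mock PBS array 3 (adjusted p = 0.811). Interferon-stimulated genes were lower as a list of 28 (median -0.19, adjusted p = 0.0468; adjusted p = 0.775 with an estimated correlation), with no member called. HERC5 was at -0.63, HERC6 at -0.39, IFIH1 at -0.80 and MX1 at -0.81. With slide as a block 2 fell, and with the replicate block 1 rose and 2 fell. The slide medians were -0.57, 0.15 and -0.09, and the call ended in 10 other settings, with adjusted p up to 0.69.

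The shares of genes whose 2 groups did not overlap, 23.1% for this comparison, compare with 10% by chance for 3 arrays against 3. With slide as a block 874 genes were called, and 1205 with the replicate number as a block. Without the arrays numbered 3, 1869 were called, and the count without any 1 array ranged from 190 (P-cadherin PBS array 2) to 596 (mock azurin array 3).

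Azurin in the P-cadherin line was accompanied by higher levels of p53 target genes. Of 29 measured members, 28 were positive, 11 rose and none fell, with a median of 0.80 (adjusted p = 3.74e-11), and 19 rose when adjusted over the list alone. With an estimated correlation the list did not pass (adjusted p = 0.413 with an estimated correlation). TP53INP1 rose by 2.07 (SE 0.319, adjusted p = 0.00815) with 1.70 at its other probe, the RNA-binding protein ZMAT3 by 1.78 (SE 0.245, adjusted p = 0.00529), SPATA18 by 1.19 and the ribonucleotide reductase subunit RRM2B by 1.17, whose other probe gave 0.57 without a call. Chosen after their values were seen, CDKN1A at 1.46, BTG2 at 1.23, FAS at 1.18, SESN1 at 1.11, PHLDA3 at 0.97 and FDXR at 0.58 also rose, as did BAX, a promoter of apoptosis, at 0.99 (adjusted p = 0.0223; other probe 0.54, not called).

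Lysosomal genes were higher as a list in the treated P-cadherin arrays, with 29 of 32 positive, 5 that rose and 1 that fell (median 0.26, adjusted p = 4.49e-06; adjusted p = 0.362 with an estimated correlation), and 6 rose and 1 fell when adjusted over the list alone. The sialidase NEU1 rose by 0.87 (SE 0.0977, adjusted p = 0.00287), the proton pump subunit ATP6V1H by 0.87 (adjusted p = 0.0288), and the proteases CTSL by 0.61 (adjusted p = 0.0254) and CTSA by 0.60 (adjusted p = 0.0269), while the sulfatase SGSH fell by 0.77 (adjusted p = 0.0398). Autophagy genes were higher as a list of 23 (median 0.17, adjusted p = 0.0292; adjusted p = 0.362 with an estimated correlation), with 3 that rose, 4 when adjusted over the list alone. GABARAPL1, which forms autophagosome membranes, rose by 2.12 (SE 0.358, adjusted p = 0.0118; 2.55 at its other probe), the receptor OPTN by 1.36 (adjusted p = 0.0342) and MAP1LC3B by 0.49 (adjusted p = 0.0388; other probe 0.61, not called). WIPI1 was at 0.80 (adjusted p = 0.077). This list's call ended with quantile normalization (adjusted p = 0.0583) and without P-cadherin PBS array 2 (0.0984) or P-cadherin azurin array 1 (0.0861) or 3 (0.0546).

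Genes of ribosome assembly were lower in the treated P-cadherin arrays, with 30 of 32 negative and a median of -0.38 (adjusted p = 4.41e-07; adjusted p = 0.377 with an estimated correlation). Of these 4 fell, and 14 when adjusted over the list alone. BOP1 fell by 0.64 (SE 0.126, adjusted p = 0.0193), PES1, its partner in 60S maturation, by 0.59 (adjusted p = 0.0226), the RNA polymerase I subunit POLR1C by 0.52 (adjusted p = 0.0316), and NOP14 by 0.52 (adjusted p = 0.0349), whose other probe was at 0.165. The call ended where no filter on dim probes was applied (adjusted p = 0.0925). DNA replication genes were lower as a list, with 35 of 40 negative and a median of -0.25 (adjusted p = 0.0292; adjusted p = 0.994 with an estimated correlation). None was called, singly or over the list alone, with UHRF1 at -0.91 (adjusted p = 0.128), E2F2 at -0.72, MCM7 at -0.49 and GINS3 at -0.42. This call ended in 4 other settings (adjusted p up to 0.943), among them leaving out P-cadherin azurin array 3 (0.244) or 2 (0.0627), and in the deposited log2 table, which is not scaled and moves the median of all genes to 0.271, the list median was 0.04. With azurin in the mock line, where DNA replication genes did not pass as a list, their medians on slides 1, 2 and 3 were -0.354, -0.317 and 0.332.

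Among single genes in this comparison, the zinc transporter SLC39A10 rose by 2.67 (SE 0.222, adjusted p = 0.00062), a 6.34-fold increase. The phosphoglucomutase-like gene PGM2L1 was at least 1.74-fold higher (adjusted p = 0.0035) and the interferon-induced factor BATF2 at least 2.77-fold higher (adjusted p = 0.0147). Bounds for the others were 1.73-fold for CCDC110, 1.66 for PDE1A, 1.53 for INS-IGF2, 1.17 for BEX1, and 1.13 for both MEIOC and PAH, and FBXL19-AS1 was at 2.33 with 0.39 and no call at its other probe. Over all tested genes, 620 were above background only on the treated P-cadherin arrays, where more probes cleared it. Of these 68 were called and 64 were higher, a direction that the rule for entering probes favours. Rises from below background cannot be told apart from the slide set. FOXI1, a forkhead transcription factor, fell by 2.52 (SE 0.244, adjusted p = 0.00147) and ZNF365 by 2.95 (adjusted p = 0.0126), with -2.67 at its other probe. ASB2 fell by 2.73, the phosphodiesterase PDE4B by 2.32 and SMCP by 2.28, and ZNF619 fell by 2.31. GSTTP2 was at least 5.15-fold lower (adjusted p = 0.00141) and C3orf20 at least 6.54-fold lower (adjusted p = 0.00193). Both were above background on no treated P-cadherin array. Of 17 tested genes of that kind, 15 were called lower and 0 higher. The median log2 change of these 17 was -2.42 here and -0.0142 with azurin in the mock line. The rule for entering probes favours a fall here, since each had to be above background in another group, so these values test no cause. The treated P-cadherin arrays shared no slide with PBS arrays. For that reason the bounds of GSTTP2 and C3orf20 cannot be told apart from dim probes reading lower on the second slides, and are no minimum azurin effect. KIR2DS4 fell by 3.28, and FGG passed the test with neither P-cadherin group above background, so no fold is given. INS-IGF2 is a readthrough transcript, GSTTP2 a pseudogene and KIR2DS4 a member of a family of near-identical receptors, so what their probes measured is uncertain.

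In the lists fixed for azurin that did not pass as lists, apoptosis regulators (adjusted p = 0.986) had 3 members that rose and 1 that fell in the P-cadherin line, the same numbers as adjusted over the list alone. They were BAX, the initiator caspase CASP9 at 0.92 (adjusted p = 0.0292), the inhibitor BIRC3, at least 1.47-fold higher (adjusted p = 0.0373), and BAD, which fell by 0.72 (adjusted p = 0.0202). Of adherens junction and desmosome genes (adjusted p = 0.436), 3 fell, also over the list alone, namely the plakophilins PKP1, 2-fold lower with -1.02 at its other probe, and PKP3 at -0.53 and the adhesion protein NECTIN1 at -0.63, while CDH2 was at -0.74 (adjusted p = 0.176). Endocytosis genes (adjusted p = 0.629) had 2 that fell, also over the list alone, VPS4A by 0.91 and FLOT1 by 0.60, with HGS at -0.33 and CAV1 at -0.67 not called. NF-kappaB targets (adjusted p = 0.652) had 2 that rose and 1 that fell, with 3 and 1 over the list alone. They were the adhesion molecule ICAM1 at 1.22 (adjusted p = 0.00287), BIRC3, and the chemokine CXCL2 at -1.07 (adjusted p = 0.0189), with NFKBIA at 0.49 not called. Of 18 metal-handling genes (adjusted p = 0.805), SLC39A10 was the 1 that rose, also over the list alone, while MT3 was at 0.52, ATOX1 at -0.43 and MT1A at -0.89 without a call.

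Over all genes, azurin in the P-cadherin line gave 1274 calls, 616 higher and 658 lower, with 1090 at least 1.5-fold and a median absolute log2 change of 0.92, and 34% of genes did not overlap between groups (10% by chance). The treated arrays had their own slides and scan session, so what this comparison does not share with azurin in the mock line, where each slide held both groups, cannot be told apart from those. The direction depended on the scaling, with 996 higher and 651 lower after quantile normalization and 632 higher and 108 lower in the deposited log2 table. The count was 202 without P-cadherin PBS array 1, 2110 without mock PBS array 3 and 6780 without the arrays numbered 3.

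In the mock line, the p53 targets were again higher as a list with azurin, with 25 of 29 positive and a median of 0.51 (adjusted p = 3.76e-06; adjusted p = 0.717 with an estimated correlation). Here 1 member rose, BAX at 1.09 (SE 0.204, adjusted p = 0.0469; other probe 0.83, not called), and 10 rose when adjusted over the list alone. TP53INP1 was at 1.33 (adjusted p = 0.0892), ZMAT3 at 1.08 (adjusted p = 0.0777) and RRM2B at 0.90 (adjusted p = 0.074). The list's median was 0.74 and 0.99 on slides 1 and 2 and -0.11 on slide 3. With slide as a block 5 members rose, with the replicate number as a block 4, and without the arrays numbered 3, 22 rose and 1 fell.

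Lysosomal genes were higher in the mock line with azurin, with 30 of 32 positive and a median of 0.32 (adjusted p = 1.6e-07; adjusted p = 0.203 with an estimated correlation), and the slide medians were 0.33, 0.27 and 0.33. NEU1 rose by 0.91 (SE 0.0977, adjusted p = 0.00515) as the only call over all genes, and 12 rose and 1 fell when adjusted over the list alone. CTSA was at 0.59 (adjusted p = 0.0751; its other, dimmer probe at 0.60 was called), ATP6V1H at 0.83 (adjusted p = 0.082), GNS at 0.63 and SGSH at -0.69. With slide as a block 3 rose and with the replicate block 5. Genes of ribosome assembly were lower, with 31 of 32 negative, a median of -0.39 (adjusted p = 3.85e-14; adjusted p = 0.203 with an estimated correlation) and slide medians of -0.37, -0.26 and -0.55. POLR1C fell by 0.64 (adjusted p = 0.0443), and 15 fell when adjusted over the list alone. RRS1 was at -0.80 (adjusted p = 0.0547), BOP1 at -0.61 and PES1 at -0.51. With slide as a block 6 fell and with the replicate block 9.

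SLC39A10 rose by 2.43 in the mock line (SE 0.222, adjusted p = 0.00261), a 5.38-fold increase, and PGM2L1 by 1.83 (adjusted p = 0.0374). The tubulin gene TUBB2B rose by 2.03 (adjusted p = 0.0419), DNAJC28 by 1.48, CCDC146 by 1.41 and DAND5 by 1.32, while GAS6-AS1 was at least 2.51-fold, ANKRD22 at least 2.19-fold and the readthrough STON1-GTF2A1L at least 1.05-fold higher. ZNF431 passed with neither mock group above background. FOXI1 was at least 5.44-fold lower (adjusted p = 0.00157) and ZNF365 at least 2.96-fold lower (adjusted p = 0.0198). ODC1, the rate-limiting enzyme of polyamine synthesis, fell by 1.62 (SE 0.218, adjusted p = 0.0187), the sterol acyltransferase SOAT2 by 1.69 (adjusted p = 0.0198), the lipase DAGLA by 1.61, MB21D2 by 1.40 and CSRP1 by 1.40. RPRML fell by 1.44, while its other probe was at -0.12 and not called. RUNX1T1 was at least 1.09-fold lower and SUGT1P4-STRA6LP, another readthrough, at least 1.18-fold. ICAM1 rose by 0.99 (adjusted p = 0.0198) as the 1 call among NF-kappaB targets (list adjusted p = 0.638; also 1 over the list alone), with BIRC3 at 0.78, RELB at 0.41 and TNFAIP2 at -0.35.

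A further 7 lists passed camera for azurin in the mock line, none with an estimated correlation. Autophagy genes had a median of 0.17 (adjusted p = 0.0291; adjusted p = 0.219 with an estimated correlation) with none called and 3 that rose over the list alone. GABARAPL1 was at 1.45, WIPI1 at 0.97, MAP1LC3B at 0.43 and GABARAP at 0.33. NRF2 targets had a median of 0.17 (adjusted p = 0.0185; adjusted p = 0.51 with an estimated correlation) with none called and 3 over the list alone, and ME1 was at 0.45, AKR1C1 at 0.69, AKR1C3 at 0.66 and FTL at 0.45. Genes of chaperones, folding and the unfolded protein response in the endoplasmic reticulum (the chaperone list below) had a median of 0.18 (adjusted p = 0.0234; adjusted p = 0.51 with an estimated correlation) with none called either way, and EDEM1 and PDIA4 were both at 0.45, SYVN1 at 0.27 and DNAJC3 at 0.29. Interferon-stimulated genes had a median of 0.24 (adjusted p = 0.048; adjusted p = 0.855 with an estimated correlation), with HERC5 rising by 1.08 (adjusted p = 0.0281) and 2 over the list alone, while HERC6 was at 0.52, STAT2 at 0.54 and IFIT1 at 1.15. Histone genes had a median of -0.17 (adjusted p = 0.00873; adjusted p = 0.855 with an estimated correlation), with H2BC12 alone falling, by 0.70 (adjusted p = 0.0267; other probe -0.34, not called), also alone over the list, and H2BC4 was at -0.37, H2BC5 at -0.32 and H2BC8 at -0.26. On slides 1, 2 and 3 the medians were 0.20, 0.14 and 0.06 for autophagy, 0.14, 0.08 and 0.36 for NRF2 targets, 0.09, 0.07 and 0.29 for chaperones, -0.05, 0.63 and 0.16 for interferon-stimulated genes and 0.03, -0.14 and -0.50 for histones. Without the arrays numbered 3, the calls for NRF2 targets (adjusted p = 0.114), chaperones (0.334) and histones (0.528) ended, and those for autophagy (0.0241) and interferon-stimulated genes (0.0241) stayed. Besides the estimated correlation, the autophagy call ended in 7 other settings (adjusted p up to 0.0798) and the interferon call in 13, with adjusted p = 0.757 and a median of 0.06 without mock PBS array 2. The chaperone call ended in 6 other settings (adjusted p up to 0.2, in the deposited log2 table), that of NRF2 targets without mock PBS array 3 (0.123) or mock azurin array 3 (0.0772), and that of histones without mock PBS array 2 (0.0722) or mock azurin array 3 (0.469). With the replicate block 2 autophagy genes, 3 NRF2 targets, 1 gene of the chaperone list and 3 interferon-stimulated genes rose over all genes, and with slide as a block 1, 1, 0 and 2.

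Sterol and fatty acid synthesis genes were higher as a list with azurin in the mock line (median 0.25, adjusted p = 0.0185; adjusted p = 0.866 with an estimated correlation) and immediate early genes lower (median -0.32, adjusted p = 0.0146; adjusted p = 0.866 with an estimated correlation), with no member of either called, over all genes or over the list alone. Immediate early genes that fell numbered 3 with slide as a block (10 over the list alone) and 2 with the replicate block (7 over the list alone). FDFT1 was at 0.50, IDI1 at 0.77, HSD17B7 at 0.83 and MVD at 0.35, and CCN1 at -0.65, KLF2 at -0.63, SPRED2 at -0.56 and JUN at -1.05. Both shifts came mainly from slide 3, with medians of -0.01, 0.00 and 0.67 for sterol genes and -0.20, -0.10 and -0.64 for immediate early genes. Both calls ended without mock PBS array 3 (adjusted p = 0.702 and 0.714), where the immediate early genes turned to a median of 0.14, and without the arrays numbered 3 (adjusted p = 0.543 and 0.281), where camera gave the sterol genes as lower with a median of 0.00. The sterol call also ended with slide as a block (adjusted p = 0.0682) and without mock azurin array 3 (0.389), and the immediate early call without mock azurin array 1 (0.0648) or 2 (0.0859).

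In the mock line 128 genes passed the adjusted test with azurin, 71 higher and 57 lower, of which 125 changed at least 1.5-fold and 128 had the same sign on all 3 slides, and 18% of genes did not overlap between groups (10% by chance). Agreement in sign over the slides is again no independent support, because the same arrays gave the calls. With slide as a block 606 genes were called and with the replicate block 926, and 36 were higher and 51 lower after quantile normalization and 2 and 10 in the deposited log2 table. The count was 9 without mock azurin array 2, 337 without mock PBS array 3 and 3692 without the arrays numbered 3. In the remaining lists fixed for azurin, BAX was the 1 call among apoptosis regulators (adjusted p = 0.398; 1 over the list alone), with BAD at -0.52, CASP9 at 0.68 and XIAP at 0.43, and SLC39A10 the 1 among metal-handling genes (adjusted p = 0.398; 1 over the list alone), with MT2A at -1.56, SLC30A1 at -0.57 and the copper pump ATP7A at 0.43, whose other 3 probes were at 0.80, 0.52 and -0.11. No endocytosis gene (adjusted p = 0.728) or junction gene (adjusted p = 0.334) was called by limma, over all genes or over the list alone, with AP2A1 at 0.42, VPS4A at -0.63, CAV1 at -0.68, TSG101 at 0.31, NECTIN1 at -0.50, PKP3 at -0.33, PKP2 at -0.37 and DSG2 at 0.23.

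The azurin responses of both lines pointed the same way for most called genes. Of the 128 genes called in the mock line, 127 had the same sign in the P-cadherin line, and 99 were called in both lines, 56 higher and 43 lower, against 2.18 and 1.87 for independent lists. None was called in opposite directions, against 2.33 and 1.75 for independent lists. Of the 1274 genes called in the P-cadherin line, 85% had the same sign in the mock line, 96.3% of those called higher and 74.5% of those called lower. Among genes above background on all 12 arrays these shares were 99.3% and 85%. For the 15 genes called lower and above background on no treated P-cadherin array the share was 53.3%. These comparisons share no arrays, and their fold changes correlated at 0.551 across genes, which are not independent replicates (covariance 0.0985; with no effect -8.93e-05 simulated with independent arrays and 0.0124 with arrays of the same number kept paired). Averaged over both lines, 2659 genes passed, 1362 higher and 1297 lower. The deposited log2 table gave 864, 621 higher and 243 lower, and the part from the P-cadherin line is confounded with slide set and session.

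For the mean azurin effect, 13 p53 targets rose and none fell (adjusted p = 5.57e-10; adjusted p = 0.532 with an estimated correlation), with 18 over the list alone. Of lysosomal genes 12 rose and 1 fell (adjusted p = 6.48e-08; adjusted p = 0.126 with an estimated correlation), with 16 and 1 over the list alone, and of autophagy genes 6 rose and 1 fell (adjusted p = 0.0199; adjusted p = 0.126 with an estimated correlation), with 7 and 1 over the list alone. All 32 ribosome assembly genes were negative, 14 fell (adjusted p = 3.66e-11; adjusted p = 0.126 with an estimated correlation) and 25 fell over the list alone. Of NRF2 targets 5 rose (adjusted p = 0.0236; adjusted p = 0.573 with an estimated correlation), also 5 over the list alone, while 3 histone genes fell (adjusted p = 0.0199; adjusted p = 0.885 with an estimated correlation), 4 over the list alone, and 2 DNA replication genes fell (adjusted p = 0.0222; adjusted p = 0.885 with an estimated correlation), 1 over the list alone.

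**Figure D2:**
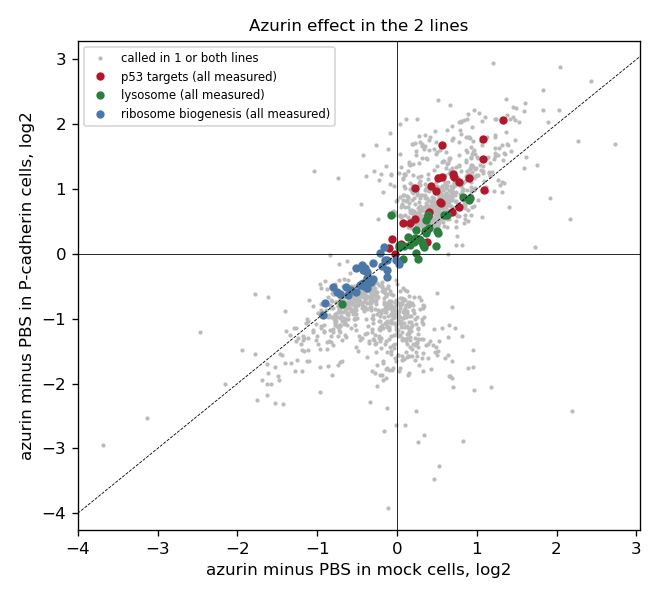
Azurin minus PBS (log2) in the mock line, horizontal axis, against the same in the P-cadherin line, vertical axis, with a grey point for each gene called in either line, coloured points for all measured p53 targets, lysosomal and ribosome assembly genes, and a dashed line of equal effect. The medians of the p53 targets are 0.51 and 0.80, those of the lysosomal genes 0.32 and 0.26 and those of ribosome assembly -0.39 and -0.38 in the mock and P-cadherin lines.

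**Figure D3:**
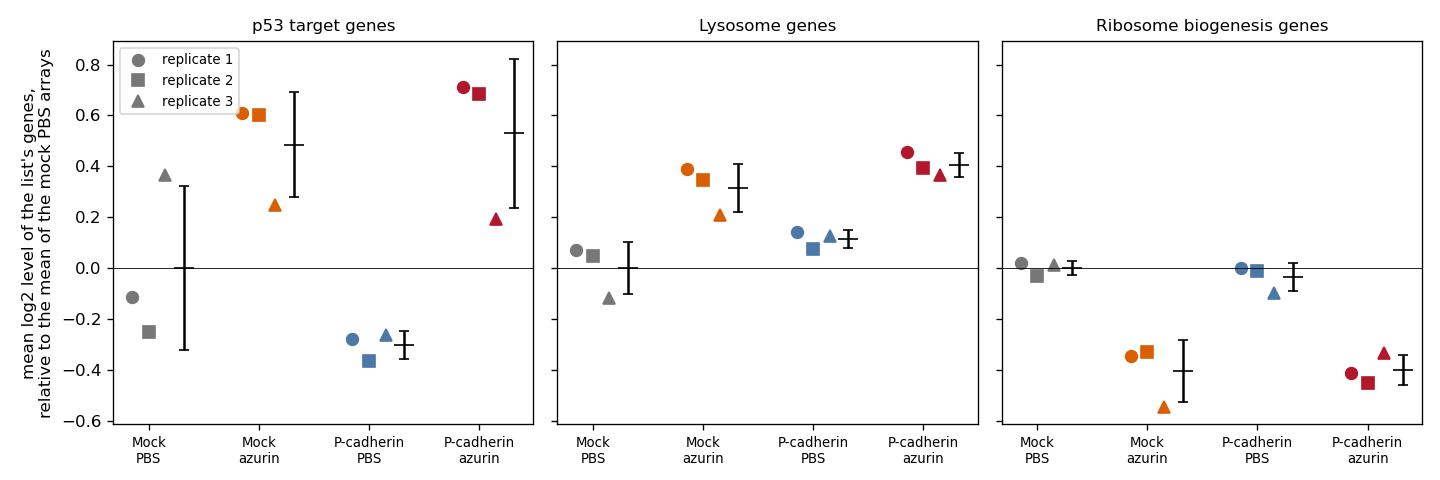
Mean log2 level of the measured p53 targets, lysosomal genes and ribosome biogenesis genes on each array, relative to the mean of the mock PBS arrays, with a symbol per replicate number and bars for the group mean and SD (n = 3). The p53 list lies at -0.115, -0.25 and 0.366 on the mock PBS arrays and at 0.609, 0.6 and 0.247 on the mock azurin arrays, so its number 3 arrays run the opposite way to the others.

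The test of whether the azurin effect differed between the lines called 5 genes with limma, all lower, while 1144 genes had an unadjusted p under 0.05. Of these 5, GSTTP2 had an adjusted p of 0.0313 and C3orf20 of 0.0442, and the other 3 were probes without a symbol. All 5 were above background on 0 treated P-cadherin arrays, so the size of their difference was not measured, and the test cannot be told apart from the slide set and scan session of those arrays. The count was 0 among probes above background on all 12 arrays, 38 after quantile normalization with 26 higher and 12 lower, 7 in the deposited log2 table with 2 higher and 5 lower, 9 with slide as a random block, 2 with the replicate number as a block, which ended the calls of GSTTP2 and C3orf20, and 0 without the arrays numbered 3. Values that did not pass were KIR2DS4 at -3.80 (adjusted p = 0.0508), TNFRSF4 at -0.94 (adjusted p = 0.0672) and TRIM6 at 0.80 (adjusted p = 0.2). FGG (adjusted p = 0.0508), P2RY10 and TRAM1L1 (0.125 for each), the lipoxygenase ALOX5 (0.126) and SYT10 (0.192) did not pass either, and no size is given for them because at least 1 group was below background on all its arrays.

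As lists, p53 targets had a more positive azurin effect in the P-cadherin line (median difference 0.32, 25 of 29 positive, adjusted p = 0.000239; adjusted p = 0.953 with an estimated correlation), with ZMAT3 at 0.70, TP53INP1 at 0.75, GADD45A at 1.12 and the nuclease AEN at 0.41. Sterol and fatty acid synthesis genes had a more negative one (median -0.23, 32 of 32 negative, adjusted p = 0.00298; adjusted p = 0.953 with an estimated correlation), with SCD at -0.42, SC5D at -1.21, MVK at -0.52 and FDFT1 at -0.30. So had mitosis genes (median -0.16, adjusted p = 0.0372; adjusted p = 0.953 with an estimated correlation), with KIF2C at -0.35, PLK1 at -0.48, HMMR at -0.35 and PRC1 at -0.22. Respiratory chain genes were at a median of -0.14 (adjusted p = 0.0416; adjusted p = 0.953 with an estimated correlation), with COX6B1 and ATP5MC1 at -0.39 and COX5B and COX8A at -0.22. No member of these 4 lists was called, over all genes or over the list alone. In the deposited log2 table, whose median over all genes was 0.383 here, the medians of the last 3 lists were positive at 0.189, 0.257 and 0.283, and their calls ended. The mitosis and respiratory chain calls also ended with the replicate block (adjusted p = 0.0537 for each), as all 4 did without mock PBS array 3 (adjusted p = 0.334, 0.868, 0.981 and 0.697). Of 24 settings, besides the estimated correlation, the call ended in 1 for p53 targets, 7 for sterol genes (adjusted p up to 0.935, without a filter), 10 for mitosis genes and 13 for the respiratory chain, and the direction given by camera turned in 3 for mitosis genes and 2 for the respiratory chain.

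With azurin in both, the P-cadherin line differed from the mock line in 873 genes, 427 higher and 446 lower, and 434 of the 453 genes called without azurin kept their sign, 335 of them called again. SGCE fell by 3.74 and the adhesion receptor CD44 by 1.20, both chosen after their values were seen. The ATF4 list was lower again (adjusted p = 0.00543; adjusted p = 0.941 with an estimated correlation), with NUPR1 falling by 0.94 and SLC7A5 by 0.84 and 3 that fell over the list alone. The histone list was lower as well (adjusted p = 0.0273; adjusted p = 0.941 with an estimated correlation), with 4 that fell and 5 over the list alone. The comparison shares the confounding with slide set and session, 24.8% of genes did not overlap (10% by chance), 2084 were called with the replicate block, 3216 without the arrays numbered 3, and 739 higher and 91 lower in the deposited log2 table.

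The effect of the P-cadherin line was also set against the effects of azurin, with which it shares control arrays. Fold changes of the untreated lines correlated with those of azurin in the mock line at 0.113 (0.499 simulated with no effect), with a covariance of 0.017 against 0.0337 simulated, and with those of azurin in the P-cadherin line at -0.245 (-0.495 simulated), with -0.049 against -0.0335. The simulation drew all arrays independently, and with arrays of the same number kept paired the covariances with no effect were 0.0221 and -0.0151. Against azurin in the P-cadherin line, 48 genes were lower with P-cadherin and higher with azurin and 23 the opposite (6.82 and 7.58 for independent lists), while 19 were higher in both and 6 lower in both (7.1 and 7.29). Against azurin in the mock line the same counts were 10 and 3 opposite (0.786 and 0.657), and 5 and 4 alike (0.818 and 0.631). The 3 control arrays were not split, since that leaves 1 comparison with a single control, and part of any excess may come from the shared arrays.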

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

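Of the tests below, those of spike-ins, of genes above background on all arrays and of other groupings of the arrays were written before their results were seen, and all others after. The results here were flagged because the azurin effects of the lines differed in the test of the interaction. The fitted log2 values were -3.94 for GSTTP2, -3.14 for C3orf20, and -2.66, -2.74 and -3.81 for 3 probes without a symbol (adjusted p = 0.0103, 0.0315 and 0.00924 in that order for the 3 probes). All 5 were above background on 0 treated P-cadherin arrays, so these values depend on signals below background and do not measure the size of a difference. As lists, p53 targets differed with camera adjusted p = 0.000239, sterol and fatty acid synthesis with 0.00298, mitosis with 0.0372 and the respiratory chain with 0.0416, and none passed with an estimated correlation (adjusted p = 0.953 for each).

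Azurin calls were 1274 in the P-cadherin line and 128 in the mock line, a ratio of 9.95, and 5 genes passed the test of the difference. Which line had more calls depended on the fit. With slide as a random block the counts turned round, to 1031 in the P-cadherin line and 1413 in the mock line. They were 3032 and 926 with the replicate block and 7138 and 3286 with array weights. Treated and PBS arrays shared slides in the mock line alone. The slides and scan session of the treated P-cadherin arrays cannot be told apart from the line as whole or part of the cause: 85% of genes called in that line had the same sign in the mock line (96.3% of those higher, 74.5% of those lower), which a shared response gives with or without a slide effect, so that the bound this share passed, written after the values were seen, decides nothing, and 7 spike-in probes gave a ratio of 3.27 with a 95% interval of 0.033 to 22. Dim probes as the whole cause of the larger count stay open, with a ratio of 5.62 among 16444 genes above background on all 12 arrays (938 and 167 calls) but 1 to 86.3 when 1 array was left out, while dim probes that read lower on the second slides may account for the 5 genes, since 98.4% of 4474 interaction calls without a filter were lower. The strictest filter left 0 interaction calls, which decides nothing about the 5 genes. Being above background on 0 treated P-cadherin arrays, they could not enter under it. Spread from the arrays numbered 3 also stays open, with a ratio of 1.84 without them (6780 and 3692 calls) but 0 and 0 calls without the arrays numbered 1 or 2. A stronger azurin response of the P-cadherin line, the biological explanation, cannot be told from these with 5 genes past the test of the difference.

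The arrays numbered 3 deviated together from their groups, with 5044 genes called for number 3 against 1 and 2. Slide 3 as the whole cause would leave the treated P-cadherin array numbered 3, which was on another slide, uncorrelated with the others, and its correlations with them were 0.273, 0.607 and 0.197. The lowest, 0.197, leaves this open, since the labelled numbering ranked first of 6 possible ones and 1 in 6 is reached by chance. The PBS arrays, which had no azurin, deviated as well (0.57 between the 2 numbered 3, which share a slide), and the design gives no group that separates number from culture or day, so no biological explanation was tested.

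CDH3 was not higher on the arrays labelled P-cadherin. A mix-up of lines among the treated arrays is argued against, as 6 of 6 treated arrays were nearer to their own untreated line over 452 genes called between the untreated lines. This test takes the labels of the untreated arrays as given, and the CDH3 difference between those arrays does not depend on the treated ones. Line labels exchanged throughout would give the same result, so the test does not bear on that. A probe outside the transferred cDNA stays open, since the only value is -0.36 from 1 probe whose position relative to the cDNA is not given in the sources used here. Lower CDH3 in this line, the biological reading, was not tested by any other measurement.

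Other groupings of the arrays were run on 20021 genes with complete values. With 6 arrays there are 10 splits, which cannot reach below 0.1. The labelled split gave 452 calls for P-cadherin without azurin (highest other 0), 1272 for azurin in the P-cadherin line (0), 128 for azurin in the mock line (2) and 871 for P-cadherin with azurin (0), and 1 of 10 splits reached the labelled count each time. For the mean azurin effect 2660 were called against 977 in the highest other, and for the interaction 5 against 1, with 1 of 100 groupings within the lines reaching the labelled count in both. These groupings ignored the replicate numbers, whereas the labelled grouping has every number in each group. Because the arrays numbered 3 deviated together, the result does not decide against a grouping by chance. The interaction calls were 2 with the replicate block and 0 without the arrays numbered 3.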

How the results depend on the processing

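Normexp, slide as a random block, the 75th percentile of shared probes and the fit without the arrays numbered 3 were chosen after seeing the data. Of 100 named calls, counted once per gene and comparison, 2099 of 2594 values under alternatives kept direction and threshold, 495 fell short of it and 0 reversed. Named calls kept in every setting that held the gene were 17 of 26 for P-cadherin without azurin. For azurin they were 13 of 46 in the P-cadherin line and 2 of 26 in the mock line (SLC39A10 and FOXI1). For the interaction they were 0 of 2. A gene missing from a setting was not counted as lost there, and other thresholds were not among these settings. For P-cadherin without azurin, SOX2 had values in 26 settings and SGCE in 27. In the mock line, FOXI1 had values in 26 and SLC39A10 in 27. Signal over background limits what can be said of dim probes. The cause of the changes below was not tested, except that a threshold alone sets some counts and fewer arrays others. Not run were normexp on mean signals, for want of that column, slide as a fixed block and scan session where treated P-cadherin arrays enter, as these cannot be separated, and list tests with a random block, whose correlation within slides was 0.409.

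Counts follow for P-cadherin without azurin (453), azurin in the P-cadherin line (1274), azurin in the mock line (128), the interaction (5), the mean azurin effect (2659), P-cadherin with azurin (873) and genes called in both azurin comparisons (99). With the replicate block they were 1205, 3032, 926, 2, 4745, 2084 and 679, and the lists past camera for the interaction went from 4 to 2. In the interaction the block ended the calls of GSTTP2 and C3orf20 and of the mitosis and respiratory chain lists (adjusted p = 0.0537 for each list), and it ended no other call of a named gene or list in the first 4 results. With array weights they were 2968, 7138, 3286, 70, 8075, 2708 and 2640, and without the arrays numbered 3, 1869, 6780, 3692, 0, 7828, 3216 and 3089. With adjusted p under 0.01 they were 153, 155, 11, 1, 735, 259 and 8. The deposited log2 table gave 176, 740, 12, 7, 864, 830 and 8. An unadjusted p under 0.05 with 1.5-fold gave 1537, 2726, 1282 and 995 for the first 4, and 2011 and 793 for the last 2, and 1.5-fold with adjusted p under 0.05 gave 1294 for the mean effect.

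With no filter on dim probes 7478, 30, 4474, 6984, 5922 and 28 were called from the second result on, and 8 lists for azurin in the P-cadherin line against 5. Normexp gave 4569 for azurin in the P-cadherin line, 939 for the interaction, with 8 lists, and 2341 for P-cadherin with azurin. Most of these calls were lower, with 14.6% higher for azurin in the P-cadherin line with no filter and 15.4% with normexp. Only the compared groups in the fit gave 245 and 3 for P-cadherin without azurin and azurin in the mock line, 465 for P-cadherin with azurin and 2 in both azurin comparisons. Slide as a fixed block gave 874 for P-cadherin without azurin and 606 for azurin in the mock line. As a random block it gave 1679 for P-cadherin without azurin, 1031 and 1413 for azurin in the P-cadherin and mock lines. It also gave 9 for the interaction and 494 in both azurin comparisons. For the interaction quantile normalization gave 38, trended robust variances 3 and probes above background on all 12 arrays 0 with limma, against 1144 with unadjusted p under 0.05 at first. With an estimated correlation 0 lists passed in any comparison, against 7, 5, 10 and 4, the deposited table gave 1 list for the interaction, and without the arrays numbered 3 there were 8 lists for azurin in the P-cadherin line and 1 for the interaction.

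Leaving out 1 array gave 190 to 596, 202 to 2110, 9 to 337, 0 to 9, 1332 to 3489, 356 to 1252 and 6 to 271 in the order above, and 4 to 10, 3 to 8, 7 to 10 and 1 to 8 lists. For P-cadherin without azurin the counts over 1.5 times away were 230 without mock PBS array 1, 242 without 2, and 191 and 190 without P-cadherin PBS array 1 and 2. For azurin in the P-cadherin line they were 836 and 2110 without mock PBS array 1 and 3, 202 and 204 without P-cadherin PBS array 1 and 2, and 210, 288 and 1979 without P-cadherin azurin array 1, 2 and 3. For azurin in the mock line they were 14, 15 and 337 without mock PBS array 1, 2 and 3, 14, 9 and 272 without mock azurin array 1, 2 and 3, 27, 28 and 68 without P-cadherin PBS array 1, 2 and 3, and 39, 34 and 209 without P-cadherin azurin array 1, 2 and 3. In that order of the 12 arrays, genes called in both azurin comparisons were 11, 12, 271, 11, 6, 215, 17, 20, 53, 20, 21 and 170, and interaction calls with limma 0, 2, 2, 3, 5, 3, 1, 2, 9, 2, 8 and 2. For the mean azurin effect, 1708 were called without mock PBS array 1, 1709 and 1419 without mock azurin array 1 and 2, 1332 and 1437 without P-cadherin PBS array 1 and 2, and 1445 and 1393 without P-cadherin azurin array 1 and 2. For P-cadherin with azurin they were 388 and 581 without mock azurin array 1 and 3, and 356 and 392 without P-cadherin azurin array 1 and 2.

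Reversed values, none of them past a test, were CDH3 with azurin in the P-cadherin line at 0.226 in the deposited table, and in the interaction at -0.0107 with normexp, -0.0534 without mock azurin array 2 and -0.0116 without P-cadherin azurin array 3 (leaving out 1 array gave up to 0.16). With normexp the interaction values of P2RY10, TRAM1L1, ALOX5, SYT10 and TRIM6 were -0.0173, -0.108, -0.345, -0.227 and -0.0816, of which all but that of TRIM6 rest on signals below background in at least 1 group. In the deposited table, whose interaction median over all genes was 0.383, those of KIF2C, HMMR, PRC1, SCD, FDFT1, COX6B1, ATP5MC1, COX5B and COX8A were 0.0671, 0.0717, 0.196, 0.00458, 0.116, 0.0268, 0.0284, 0.196 and 0.201.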

Other observations

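The genes and lists here were looked up after the values were seen, and the test of the arrays numbered 3 was also chosen then. Between the untreated lines, CD44, an adhesion receptor and stem cell marker, fell by 1.38 (SE 0.126, adjusted p = 0.000318) and TIMP3, an inhibitor of matrix proteases, rose by 1.41 (SE 0.137, adjusted p = 0.00044). CALD1 fell by 1.15 and TNFAIP2 by 0.96, the complement protease C1R by 1.08 (adjusted p = 0.038), the protease inhibitor SERPINA1 by 0.98 and the transporter ABCC2 by 0.85, while the fatty acid elongase ELOVL2 rose by 0.93. The epithelial cadherin CDH1 was at 0.01 and the estrogen receptor ESR1 at 0.10, neither called.

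With azurin in the P-cadherin line, a comparison confounded with slide set and session, the protein C receptor PROCR rose by 1.50 (SE 0.185, adjusted p = 0.00393), and it rose by 1.14 in the mock line (adjusted p = 0.0325). C1S rose by 1.54, the haem oxygenase HMOX1 by 1.26 (adjusted p = 0.0488), HERC5 by 1.24 and the integrin ITGA6 by 0.93, while the ephrin receptor EPHA2 fell by 1.34 (adjusted p = 0.019), the transporter ABCG2 by 1.00 (adjusted p = 0.0146) and the integrin ITGA3 by 0.76.

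The lists without a call in the comparisons of P-cadherin without azurin, azurin in the P-cadherin line and azurin in the mock line had adjusted p, in that order, of 0.321, 0.805 and 0.783 for tight junctions, 0.132, 0.986 and 0.156 for matrix proteases, 0.797, 0.609 and 0.218 for receptor and adhesion kinases, 0.795, 0.986 and 0.743 for estrogen response, 0.111, 0.629 and 0.638 for luminal markers, 0.755, 0.387 and 0.551 for stem cell markers and 0.258, 0.958 and 0.521 for mesenchymal genes. They were 0.0636, 0.368 and 0.638 for complement, 0.899, 0.629 and 0.398 for heat shock, 0.907, 0.265 and 0.638 for hypoxia and glycolysis, 0.734, 0.907 and 0.638 for innate sensing and 0.321, 0.986 and 0.415 for reference genes. Mitosis (0.11, 0.805 and 0.0782) and respiratory chain genes (0.56, 0.318 and 0.638) did not pass either. Markers of fibroblasts (0.492, 0.986 and 0.925), leukocytes (0.62, 0.135 and 0.718), endothelium (0.79, 0.767 and 0.718) and blood or liver (0.584, 0.932 and 0.743) did not pass, and limma called none of their members over all genes. Adjusted over the list alone, 1 fibroblast marker fell and 1 of blood or liver rose with azurin in the P-cadherin line, and 1 of blood or liver fell for P-cadherin without azurin.

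The arrays numbered 3 differed from numbers 1 and 2 within groups in 5044 genes, 2371 higher and 2673 lower. Of 29 immediate early genes 18 rose and 1 fell (adjusted p = 4.51e-09; adjusted p = 0.627 with an estimated correlation), while 19 of 40 DNA replication genes fell (adjusted p = 1.79e-07; adjusted p = 0.85 with an estimated correlation) and 13 of 18 heat shock genes fell (adjusted p = 3.04e-06; adjusted p = 0.627 with an estimated correlation). The ATF4 list was higher (0.00336; adjusted p = 0.85 with an estimated correlation), as were kinases (0.00848; 0.302) and metal-handling genes (0.0238; 0.757), and basal markers were lower (0.0193; 0.627). The collagen gene COL13A1 rose by 3.52, the potassium channel KCNJ12 by 2.98 and SHC4 by 2.73, and the keratin KRT1 fell by 3.37 and NPTX1 by 3.31.

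Among the genes called for azurin in the P-cadherin line, 6 were above background in neither group of that line.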
